A study of Homo sapiens with 6 samples.

How the data were processed

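Human nucleus pulposus cells were cultured and transduced with lentivirus expressing control or FIH-1 short hairpin RNA, and total RNA was column-purified, treated with DNase, amplified and biotin-labelled with NuGEN Ovation kits, per the labels' protocols. There were 6 arrays, 3 in each group, and the group and replicate number of each came from its title. The authors deposited a table of linear probe set intensity, which its name calls raw, and a second table of log2 values. The software, background correction, normalization and genome build are not given in the sources used here. From the values, every deposited intensity was at least 16, and 5 of the 6 arrays had nearly equal quantiles, with medians of 35.4 to 38.3 and 95th percentiles of 365 to 369, whereas silenced replicate 3 had 29.4 and 260. The intensities therefore look already normalized between arrays, by a step that is not stated. The deposited log2 table equalled the log2 of the intensity minus each probe set's median over the 6 arrays, with a largest difference of 1.96e-06; its column medians were 0.00, 0.01 and -0.01 in the controls and 0.00, 0.02 and -0.14 in the silenced arrays, and their direction was therefore known. A constant of 16 in the signals, added or set as a floor, compresses the fold changes of dim genes, and there were no detection calls, so the 95th percentile of the olfactory receptor genes of each array, chosen after the data were examined, was used as the level of background for the named genes. All columns of per-sample values were used.

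The design fixed before the data were examined was to normalize the intensity table, or, if it proved to be normalized already, to use the log2 table without further normalization. The second branch applied. The median log2 signal of each probe set was added back so that levels could be given, which changes no difference. Of 28869 probe sets, 19310 had 1 gene in the platform's annotation table, 1752 several and 7807 none, and only those with 1 gene were used. Of these, 19279 were matched through the Entrez identifier to a current RefSeq gene record of GRCh38.p14, used for names only, and 0 symbols changed. For 685 genes with several probe sets the one with the highest mean was kept, leaving 18377 genes. For the 23 tested genes that are Y-linked or XIST no value is reported. CA9, one of the genes to be named in any case, is not analysed here. No coordinates are given because the build of the array annotation is not named.

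Silenced and control arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, no covariate and no replicate number in the model. For HIF1AN an exact two-sided permutation test was also run. Shifts of 21 gene lists, covering HIF, Notch, stress, inflammation, growth, disc matrix and other cell types, were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as alternatives. Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names HIF1AN; up to 12 genes per direction with the largest change among those past the threshold whose groups do not overlap, filled to 8 per direction by smallest p where fewer qualify; from each list up to 4 members past the threshold, or else the 2 with the smallest p; and 23 fixed genes of the HIF and Notch pathways and the disc matrix, 22 of which were measured. Provisional loci and small non-coding RNAs were passed over when filling. Abundant genes named to describe silenced replicate 3 were picked after their values were seen. Figures were drawn with matplotlib 3.10.9.

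The alternatives fixed beforehand were quantile normalization on top, the intensity table as the source, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, normexp background correction with an offset of 50, the replicate number in the model, eBayes with trend and robust, array weights, and leaving out each array. After the data were examined, a median shift, replacing the constant of 16 by 1, silenced replicate 1 alone against the controls, the 4 arrays without control replicate 3 and silenced replicate 3, the 5 arrays without silenced replicate 3 quantile normalized, and the set tests with an estimated correlation and with fry over those 5 arrays were added. Array weights were computed gene by gene, a method chosen after limma's default did not converge on these arrays.

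The fits were tested on simulated data of 18377 genes with the real genes' means and 200 changed genes, 100 by 1 and 100 by 2 on the log2 scale. The spread of each gene was that within groups over 5 arrays, after limma's moderation across genes. With 1 of 6 arrays as discordant as silenced replicate 3, the comparison recovered 0% of the genes changed by 1 and 0% of those changed by 2. With array weights it recovered 98% and 100% with 21 false calls, over 5 arrays 94% and 100% with 20 false calls, and over 6 arrays with none discordant 100% of each with 13 false calls. The simulated discordant array differed from the others by random amounts unrelated between genes. Because the simulated spread was already moderated, it differed less between genes than the real spread does. The shares recovered may therefore be higher than the real comparison can reach. An absence of calls in the real data does not show an absence of change.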

Results

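Gene expression was measured in human nucleus pulposus cells, the cells of the gel-like core of the intervertebral disc, after transduction with lentivirus carrying a control short hairpin RNA or one against FIH-1. FIH-1 is the asparaginyl hydroxylase, encoded by HIF1AN, that inhibits the transcriptional activity of hypoxia-inducible factors (HIF). There were 3 control arrays and 3 silenced arrays, each an Affymetrix gene array of amplified total RNA, and 18377 genes were tested. Nothing in the labels states whether the replicates came from separate donors or cultures, so the p-values measure the spread between these samples, which may be technical. The precision of each value is limited by the number of arrays.

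Several abundant transcripts, picked after their values were seen, were at similar levels in 5 of the 6 arrays and far lower in silenced replicate 3, while others differed less or the other way. GAPDH, a glycolytic enzyme, had a log2 signal of 8.38 in silenced replicate 3 and 11.46 to 11.63 in the others. EEF1A1, a translation elongation factor, had 8.0 against 11.51 to 11.72, and ACTB, cytoplasmic actin, 7.27 against 10.96 to 11.91. ENO1, the glycolytic enolase, had 4.15 against 9.82 to 10.06, and TIMP1, an inhibitor of matrix metalloproteinases, 5.93 against 11.32 to 11.54. VIM, the intermediate filament vimentin, had 9.67 against 10.96 to 11.35, and COL1A1, type I collagen, was higher, at 10.47 against 8.02 to 8.49. The median of 61 ribosomal protein genes differed by -1.93 in log2 signal between this array and the controls, while the median of 336 olfactory receptor genes, which few cell types outside the nose express, differed by 0.61. The share of olfactory receptor genes above the control mean was 69.9% in this array, 70.2% in silenced replicate 2, where their median differed by 0.14, and 47.9% to 50.6% in the other arrays. Across genes, which are not independent replicates, Pearson's r was 0.974 to 0.985 between the controls, 0.949 to 0.986 among the 5 other arrays, and 0.297 to 0.387 between silenced replicate 3 and each of them. In this array 18.6% of genes had a signal below 17, within 1 unit of the lowest value in the table, against 1.34% to 1.94% in the others. The design fixed in advance uses all 6 arrays, so each result is given for all 6 and then for the 5 arrays without silenced replicate 3.

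**Figure D1:**
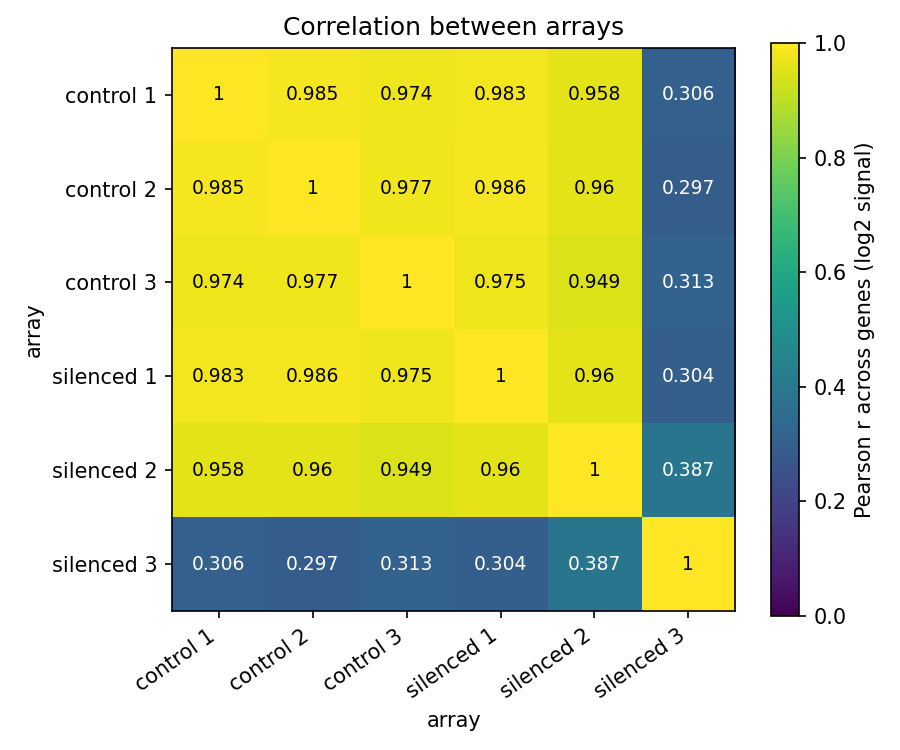
Pearson's r across 18377 genes (log2 signal) between each pair of arrays, with the value written in each cell and coloured from 0 to 1. The 5 other arrays correlate with each other at 0.949 or more, and silenced replicate 3 correlates with each of them at 0.387 or less.

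The first question was whether the targeted transcript was lower in the arrays labelled as silenced. HIF1AN was lower in all 3 silenced arrays than in any control array. Its log2 signal was 5.57, 5.49 and 5.10 in control replicates 1, 2 and 3, and 4.54, 4.43 and 4.0 in silenced replicates 1, 2 and 3, the last close to the lowest value in the table, a signal of 16. The group means were 5.39 ± 0.25 (SD, n = 3) and 4.33 ± 0.29 (SD, n = 3), a 2.08-fold lower geometric mean signal (log2 change -1.06, SE 0.32). Without silenced replicate 3 the signal was 1.86-fold lower (log2 change -0.90, SE 0.18). The silenced arm was not above background: the olfactory receptor genes had a median log2 signal of 4.44, 4.60 and 4.99 and a 95th percentile of 5.14, 5.52 and 6.22 in silenced replicates 1, 2 and 3. Control replicates 1 and 2 lay above that percentile of their own arrays (5.25 and 5.22) and control replicate 3 below it (5.30). The folds are therefore those of the signal, which understate a change in transcript level where 1 group is at background. HIF1AN ranked 2 of 18377 genes by p over 6 arrays and 3 over 5 arrays, but limma's adjusted p was 0.606 and 0.705. The exact two-sided permutation test gave p = 0.1 in both cases, the smallest p that 3 arrays against 3, or 3 against 2, can give. The size of the change depended on the treatment of the background: it was -2.79 with the constant of 16 in the signals replaced by 1, and -0.49 after normexp background correction, which adds an offset of 50.

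**Figure D2:**
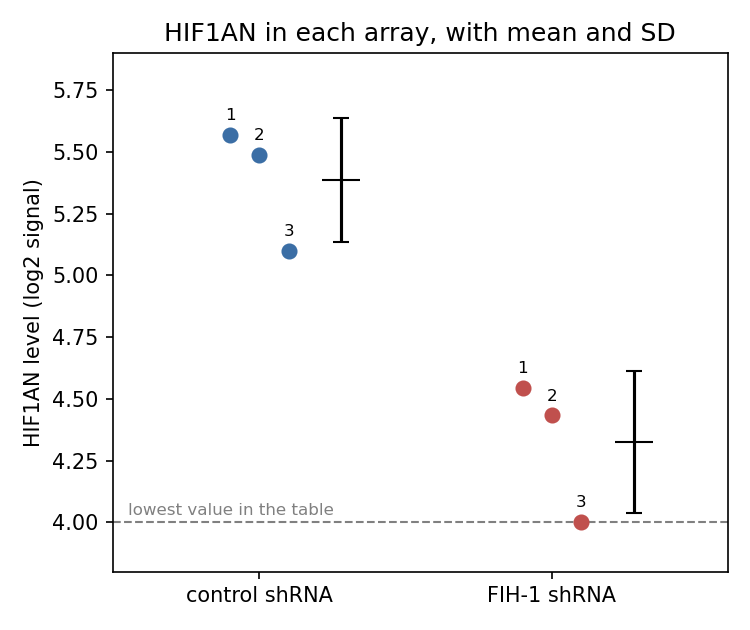
Log2 signal of HIF1AN in each of the 6 arrays (points, numbered by replicate), with the mean and SD of the 3 arrays of each group beside them; the dashed line is the lowest value in the table. The silenced arrays lie between 4.0 and 4.54 and the control arrays between 5.10 and 5.57.

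The second question was which genes differed between FIH-1-silenced and control cells. HAPLN1, the link protein that anchors aggrecan to hyaluronan in cartilage and disc matrix, had the smallest p over 6 arrays: its mean log2 signal was 4.90 in silenced and 6.51 in control cells (log2 change -1.61, SE 0.46; -1.16, SE 0.21, without silenced replicate 3). Lower in every silenced array than in any control were also WBP4, a splicing factor (-1.24, SE 0.42), PBX3, a homeodomain transcription factor (-0.90, SE 0.31), TINAGL1, a matricellular protein (-0.83, SE 0.30), FBXO5, an inhibitor of the anaphase-promoting complex (-0.90, SE 0.32), ANKRD46 (-1.03, SE 0.35) and METTL23, a methyltransferase (-1.09, SE 0.38). Higher in every silenced array than in any control were CBFA2T3, a transcriptional corepressor (1.33, SE 0.46), CCL26, the chemokine eotaxin-3 (1.11, SE 0.38), NLGN3, a synaptic adhesion protein (0.91, SE 0.32), RTP5 (1.45, SE 0.51), NKX2-4, a homeodomain transcription factor (1.14, SE 0.41), PALM3 (0.97, SE 0.35) and ZDHHC19, a palmitoyltransferase (0.96, SE 0.36). Without silenced replicate 3 the log2 changes of these genes were -1.16 to -0.72 and 0.74 to 1.04. Of the 75 named genes, 8 were at or below the 95th percentile of the olfactory receptor genes in every silenced array, a limit chosen after the data were seen: HIF1AN, ANKRD46, TINAGL1, FBXO5, POGLUT1, AURKA, NCAM1 and NOTCH1. In every control array this held for 5, CCL26, PALM3, KDM4B, HEY1 and COL11A2. The log2 changes of these genes are differences from a group at background and not measured sizes. HAPLN1, WBP4, PBX3, METTL23, APH1B, ASNS, TGFB3, EGLN3, HES1 and IBSP were above that level in only 1 of the 3 silenced arrays. The sizes of their changes are therefore limited by background too. TRIM52, CSF1R, SPP1 and APBA3 were not above that level in any array, so no change is given for them.

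None of these genes passed the test. With limma, 0 genes were higher and 0 lower at an adjusted p below 0.05, and the lowest adjusted p was 0.606. Below an unadjusted p of 0.05 there were 85 genes, where 919 are the number that chance gives, and below 0.01 there was 1, HAPLN1, against 184. Without silenced replicate 3, again 0 genes passed in either direction; 1243 genes lay below an unadjusted p of 0.05 and 143 below 0.01, 77 of them higher and 66 lower in the silenced cells. In silenced cells 1295 genes lay above and 1468 below all controls in every array, together 15.0% of the genes, where chance gives 10%. Over 5 arrays the counts were 2455 and 1868, together 23.5%, where chance gives 20%. The median log2 change of all genes was -0.16 over 6 arrays and 0.02 over 5, so the values of single genes over 6 arrays are read against that shift.

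Weighting each array by its agreement with its group was the only alternative in which genes passed: 26 rose and 10 fell at an adjusted p below 0.05. Silenced replicate 3 had a weight of 0.0282 there, silenced replicates 1 and 2 had 0.870 and 1.81, and the controls 1.95 to 3.84. The weights were estimated from these same 6 arrays and then treated as known. Leaving silenced replicate 3 out altogether gave 0 genes past the threshold. The calls therefore depend on the weighting, and their adjusted p-values may be too small. HIF1AN fell by 0.96 on the log2 scale in this fit (adjusted p = 0.0172; 0.0172 to 1.00 over the alternatives). HAPLN1 fell by 1.09, ANKRD46 by 1.09, WBP4 by 0.90 and TINAGL1 by 0.87, and so did COX7B, a subunit of cytochrome c oxidase, by 0.93 and MLLT3, a subunit of the super elongation complex, by 0.90 (log2 changes of -1.09, -1.09, -0.90, -0.87, -0.93 and -0.90). CBFA2T3 rose by 1.28, FOXF1, a forkhead factor used as a nucleus pulposus marker, by 0.96, CCL26 by 0.86 and NLGN3 by 0.84. Of the 36 genes, 21 were higher and 9 lower in both silenced replicates 1 and 2 than in all controls, and in 5 silenced replicate 1 lay within the range of the controls. In 33 of the 36, silenced replicate 2 lay farther from the control mean than silenced replicate 1. The same arrays chose the genes, so these counts are not a replication. RPL32P3 and RGN, with the smallest p, are among the 5 with silenced replicate 1 within the range of the controls: RGN had 9.66 in silenced replicate 2 and 7.22 in silenced replicate 1, against 6.20 to 7.29 in the controls. COX7B, MLLT3, RPL32P3, RGN and RCE1 were picked after their values were seen.

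A further question, which the function of FIH-1 gives, is whether genes induced through HIF moved. Over all 6 arrays the HIF target list, 40 of whose 42 genes were measured, was lower in silenced cells, with 35 members below and 5 above 0 and a median log2 change of -0.69, against -0.16 for all genes (camera with a preset correlation, adjusted p = 0.0169). The call was lost with an estimated correlation (adjusted p = 0.798) and with fry (adjusted p = 0.618), and without silenced replicate 3 the median was 0.03, with 22 members above and 18 below 0 (adjusted p = 0.873). In silenced replicate 3, where ENO1 and GAPDH of this list were at the low levels given above, the list's median difference from the mean of the controls, less that of all genes, was -1.58, against 0.04 and -0.05 in silenced replicates 1 and 2. Control replicates 1, 2 and 3, each set against the other controls, had 0.12, 0.14 and -0.23. With control replicate 3 left out as well, the median over 4 arrays was -0.03, with 26 members below and 14 above 0 (adjusted p = 0.381). No member passed, either adjusted over all genes or adjusted over the list alone. VEGFA, the angiogenic growth factor, had a log2 change of -0.80 (SE 0.55) over 6 arrays and -0.17 (SE 0.19) over 5. SLC2A1, a glucose transporter, had -0.77 (SE 0.76) and 0.20 (SE 0.16). PGK1 and LDHA, glycolytic enzymes, had -1.73 and -0.86 over 6 arrays and -0.22 and -0.11 over 5. BNIP3, a mitophagy receptor, had -0.995 and 0.06, and EGLN3, a HIF prolyl hydroxylase, 0.10 and 0.18. LOX, which cross-links collagen, and KDM4B, a histone demethylase, had the smallest p over 6 arrays in the list, at -1.57 (SE 0.89) and 0.55 (SE 0.34), and -0.45 and 0.33 over 5. Over the 4 arrays without control replicate 3, LOX had -0.18 and KDM4B 0.20, and EPAS1 and BNIP3, above 0 over 5 arrays, had -0.02 and -0.01.

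Among the HIF subunits, HIF1A had a log2 change of -1.66 (SE 1.15) over 6 arrays and -0.13 (SE 0.18) over 5, EPAS1, which encodes HIF-2 alpha, -1.46 and 0.31, and ARNT, their dimerization partner, -0.74 and 0.28. VHL, the ubiquitin ligase subunit that targets HIF alpha, had -0.74 and -0.16. The list of 16 measured HIF regulators had a median of -0.70 over 6 arrays (adjusted p = 0.387) and 0.06 over 5 (0.750). The 19 measured FIH-1 substrates had -0.85 (adjusted p = 0.214) and -0.07 (0.812), with FEM1B at -1.18 (SE 0.66) and -0.36 (SE 0.15). With control replicate 3 left out as well, the median of the substrates was 0.02. No member of either list passed, adjusted over all genes or adjusted over the list alone.

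Notch receptors are substrates of FIH-1, which makes the Notch pathway a further group to compare. Its 34 measured members had a median log2 change of -0.24 over 6 arrays, 23 below and 11 above 0 (adjusted p = 0.411). The median was 0.05 over 5 arrays, 15 below and 19 above 0 (adjusted p = 0.827). Over the 4 arrays without control replicate 3 and silenced replicate 3 it was -0.03, with 18 members below and 16 above 0. The list did not pass there, and the side of 0 on which most members lay depended on control replicate 3. Whether the study picked this pathway from these samples is not given in the sources used here, so its count is not taken as independent evidence of a direction. APH1B, a gamma-secretase subunit, had -0.78 (SE 0.38) over 6 arrays and -0.46 (SE 0.18) over 5. POGLUT1, which glycosylates Notch, had -0.74 (SE 0.37) and -0.43 (SE 0.16). The sizes of both changes are limited by background in the silenced arrays, as given above. NOTCH1 had -0.29 and 0.12, NOTCH2 -1.14 and 0.04, NOTCH3 0.71 and 0.31, and the ligand JAG1 -0.31 and 0.05. The 8 Notch target genes had a median of 0.26 over 6 arrays and 0.18 over 5, with 6 of 8 above 0 in both (adjusted p = 0.120 and 0.334). HES4 was at 0.79 (SE 0.42) and 0.40 (SE 0.20), HEY1 at 0.96 over 6 arrays, with no array above background among the other 5, and HES1 at 0.69 and -0.07. No member of the 2 Notch lists passed, adjusted over all genes or adjusted over the list alone.

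Among the genes that define disc cells and their matrix, HAPLN1 was the one member that passed when adjusted over the list alone, in the cartilage matrix list and only without silenced replicate 3 (adjusted p = 0.00706 over its 26 genes; adjusted p = 0.705 over all genes). ACAN, the core protein of aggrecan, had a log2 change of -0.87 (SE 0.78) over 6 arrays and 0.12 (SE 0.17) over 5. COL2A1, the type II collagen of cartilage, had 0.32 and 0.06, SOX9, the chondrogenic transcription factor, -0.27 and 0.31, and COL11A2, a minor fibrillar collagen, 0.59 and 0.38 by its brightest probe set, while its other probe sets had 0.11 and 0.12 over 6 arrays and 0.00 and 0.00 over 5. The cartilage list had a median of -0.00423 over 6 arrays (adjusted p = 0.438) and 0.11 over 5 (0.334). The 16 nucleus pulposus markers had -0.48 (adjusted p = 0.868) and 0.17 (0.589), with FOXF1 at 0.87 (SE 0.36) and 0.78 (SE 0.26) and NCAM1, an adhesion molecule, at -0.82 (SE 0.34) and -0.58 (SE 0.17). The 21 matrix proteases and inhibitors had -0.50 (adjusted p = 0.333) and -0.01 (0.795). MMP3, stromelysin-1, was at -1.63 (SE 0.85) and -0.54 (SE 0.20), MMP11 at 0.81 and 0.52, the aggrecanase ADAMTS1 at -1.82 and -0.62, and ADAMTS5, another aggrecanase, at -0.50 and 0.04.

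Of the 21 gene lists, 8 passed an adjusted p of 0.05 over 6 arrays with camera's preset correlation, and none of the 8 passed with an estimated correlation (adjusted p = 0.798 for each) or with fry (adjusted p = 0.618 for each). Lower were HIF targets, cholesterol synthesis (median -0.85, adjusted p = 0.0169), TGF-beta and BMP signalling (-0.81, 0.0384), fibroblast and contractile genes (-0.83, 0.0384), the unfolded protein response (-0.64, 0.0384) and heat shock genes (-0.79, 0.0397). Higher were leukocyte markers (0.34, 0.0169) and endothelial markers (0.44, 0.0384). The median levels of these lists in the controls were 4.69 and 5.22, no higher than the olfactory receptor genes' 95th percentile there (5.22 to 5.30). Many of their genes were thus at background, and whether such cells were present was not tested. Their median differences from the mean of the controls, less that of all genes, were 1.38 and 1.68 in silenced replicate 3, where the olfactory receptor genes were also higher than in the controls. Against 10000 random lists of the same size and control level, the median difference of silenced replicate 3 from the controls lay at percentile 91.5 for the leukocyte list and 98.5 for the endothelial list, the only one of the 21 lists outside the central 95%. Without silenced replicate 3 only cholesterol synthesis passed, with 16 of 17 measured members below 0 and a median of -0.30 (adjusted p = 0.000304; adjusted p = 0.823 with an estimated correlation). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, was at -0.40 (SE 0.22) and FDPS, farnesyl diphosphate synthase, at -0.45 (SE 0.26) over 5 arrays; control replicate 3 differed from the other controls by 0.66 on this list, less the median of all genes, against -0.38 and -0.23 for the other controls and -0.14 and -0.42 for silenced replicates 1 and 2. With control replicate 3 left out as well, cholesterol synthesis no longer passed (median -0.11, 15 of 17 members below 0, adjusted p = 0.205), and INSIG1 and FDPS were at -0.18 and -0.16.

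**Figure D3:**
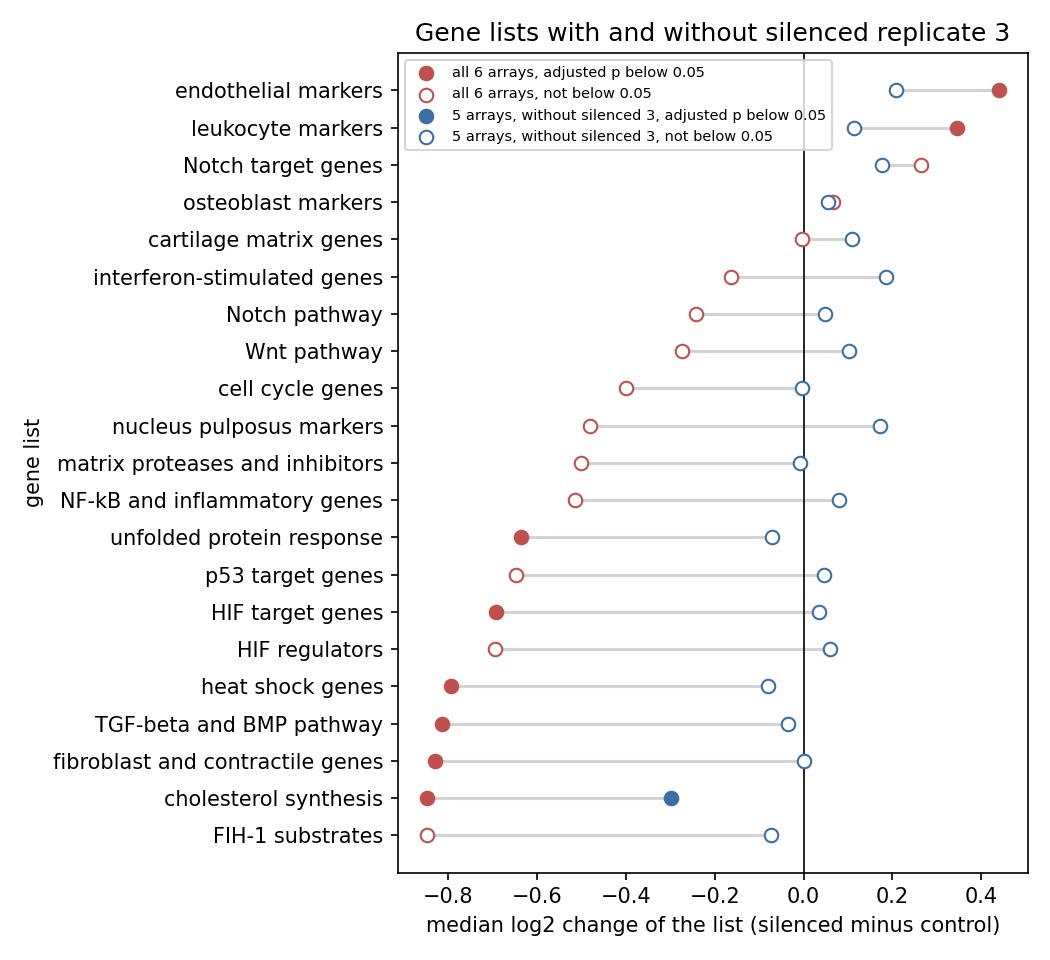
Median log2 change (silenced minus control) of each of the 21 gene lists over all 6 arrays (red) and over 5 arrays without silenced replicate 3 (blue), joined by a grey line; filled points have a camera adjusted p below 0.05 with the preset correlation. The HIF target list moves from -0.69 to 0.03, and cholesterol synthesis is the only list filled over 5 arrays, at -0.30.

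The remaining called lists had medians between -0.08 and 0.21 over 5 arrays. Of the 75 named genes, 16 had a change over 5 arrays more than 1.5 times that over the 4 arrays without control replicate 3, and 3 had the other sign. Some changes were larger over the 4 arrays and were not counted. Among them were VEGFA (-0.17 over 5 arrays and -0.31 over 4), HIF1A (-0.13 and -0.23) and COL1A1 (0.17 and 0.31). TGF-beta and BMP genes had -0.04 (adjusted p = 0.750), or 0.04 without control replicate 3 as well. TGFB3 was at -0.83 over 6 arrays and -0.53 over 5 and NOG, the BMP antagonist noggin, at 0.93 and 0.43. Fibroblast and contractile genes had 0.00 (adjusted p = 0.812), with TAGLN, a smooth muscle actin-binding protein, at -1.79 and -0.60, or -0.24 without control replicate 3 as well, and COL1A1 at 0.87 and 0.17. The unfolded protein response had -0.07 (adjusted p = 0.317), with XBP1 at -1.20 and -0.30 and ASNS at -0.96 and -0.49, and heat shock genes had -0.08 (adjusted p = 0.334), with HSP90AA1 at -1.14 and -0.18 and HSPH1 at -0.79 and -0.20. Leukocyte and endothelial markers had 0.11 and 0.21 (adjusted p = 0.213 for both), with TYROBP at 0.78 and 0.53, VWF at 0.79 and 0.36 and ROBO4 at 0.53 and 0.24.

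The other lists did not pass over 6 or over 5 arrays. Cell cycle genes had medians of -0.40 and -0.00339 (adjusted p = 0.110 and 0.750); within them AURKB and AURKA, mitotic kinases, were at 0.84 and -0.68 over 6 arrays and 0.52 and -0.45 over 5. With control replicate 3 left out as well, the cell cycle list passed with the preset correlation, 29 members below and 8 above 0 with a median of -0.18 (adjusted p = 0.000171; adjusted p = 0.799 with an estimated correlation). Genes of NF-kB and inflammation had -0.52 and 0.08 (adjusted p = 0.375 and 0.589), with TNFAIP3 at -1.04 and -0.27 and LIF at -0.72 and -0.22. Interferon-stimulated genes had -0.16 and 0.18 (adjusted p = 0.647 and 0.213), with OAS3 at 0.66 and 0.32 and IRF7 at 0.73 and 0.36. Targets of p53 had -0.65 and 0.05 (adjusted p = 0.148 and 0.880), with BBC3 at 0.86 and 0.39 and FAS at -0.86 and -0.12. Wnt pathway genes had -0.27 and 0.10 (adjusted p = 0.978 and 0.748), with WNT5B at -0.80 and -0.49 and NKD2 at 0.99 and 0.43. Osteoblast markers had 0.07 and 0.06 (adjusted p = 0.375 and 0.520), with IBSP at 0.53 and 0.05. With control replicate 3 left out as well, some medians that were above 0 over 5 arrays lay below 0. That of NF-kB and inflammation was -0.08, 13 members below and 8 above 0, that of p53 targets -0.03 and that of the Wnt pathway -0.00409. None of these lists passed there. Camera compares the test statistics of a list, not its log2 changes, with those of all other genes. Its direction can therefore differ from the sign of the log2 changes. Over 6 arrays it was upward for the interferon, cartilage and Wnt lists although their medians were below 0. Over 5 arrays it was downward for the Notch pathway, whose median and mean were above 0. The same held over 5 arrays for the FIH-1 substrates, whose mean was above 0, and for the fibroblast list, whose median was 0.00.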

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

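The median shift, the replacement of the constant of 16 by 1, silenced replicate 1 alone against the controls, the 4 arrays without control replicate 3 and silenced replicate 3, the 5 arrays quantile normalized, and the set tests with an estimated correlation and with fry over 5 arrays were chosen after seeing the data. HIF1AN was lower in silenced cells under every alternative that tested it, from -2.79 to -0.49 on the log2 scale; it was among the dimmest 30% of genes, so leaving these out gave no value. It passed the threshold only with array weights (-0.96). Array weights also gave 26 genes higher and 10 lower, 802 below an unadjusted p of 0.01, 1 list past the threshold, and medians of -0.0105 for HIF targets and 0.00804 for the Notch pathway; there silenced replicate 3 has almost no weight. All other alternatives, leaving out silenced replicate 3 included, gave 0 genes past the threshold in both directions. The calls thus depend on weights estimated from the same arrays.

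The count of genes below an unadjusted p of 0.01 was 1 over 6 arrays. It was 0 without the dimmest 30% of genes, 6 with trend and robust, 2 after a median shift, 2 with the constant replaced, 86 for silenced replicate 1 alone, 85 over the 4 arrays, 141 for the 5 arrays quantile normalized, and 0 to 143 when 1 array was left out, with 143 without silenced replicate 3 and 34 without silenced replicate 1.

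The count of lists past the threshold was 8. It was 0 without the dimmest genes, 3 with the constant replaced, 0 for silenced replicate 1 alone, 1 over the 4 arrays, 1 for the 5 arrays quantile normalized, 0 with an estimated correlation or fry over 6 or over 5 arrays, and 1 to 8 when 1 array was left out, with 1 without silenced replicate 3. The HIF target list stayed at -0.69 but no longer passed with an estimated correlation or fry, and had -0.72 without the dimmest genes (adjusted p = 0.103; 0.00309 to 0.995 over the alternatives). When 1 array was left out its median was -1.12 to 0.03. Without silenced replicate 3 it was 0.0349, close to the 0.0245 of all genes there, and the list did not pass with any set test. This median is the same value whichever set test is run. The list's median was also above 0 for silenced replicate 1 alone (0.0547) and over the 5 arrays quantile normalized (0.0514). Over the 4 arrays it was -0.0302 and the list did not pass. The Notch pathway had -0.53 to 0.05 when 1 array was left out, 0.0472 without silenced replicate 3 and 0.0276 over the 5 arrays quantile normalized. It was below 0 over the 4 arrays (-0.0318) and for silenced replicate 1 alone (-0.0333). Where silenced replicate 3 is the only array removed, the change follows from its removal; for the other settings the cause was not tested. Silenced replicate 1 alone is an arm of 1 array, assumed to vary like the 3 controls, which give all of the spread, and its values also lack silenced replicate 2.

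Quantile normalization, the intensity table as the source, the mean of a gene's probe sets and normexp left 0 genes past the threshold and the HIF target list lower and past it, with 8 lists called, or 6 after quantile normalization. The median log2 change of all genes was -0.16 over 6 arrays, -0.08 after quantile normalization, -0.10 after the median shift and -0.45 with the constant replaced. Of 1401 values of named genes under alternatives, 11 passed the threshold and 66 had the other sign; 12 named genes differ in sign without silenced replicate 3. Deviations of same-numbered arrays from their group means correlated at 0.01, 0.09 and 0.08 across genes, under the 0.1 needed to take the replicate numbers as pairs, but silenced replicate 3 dominates the mean of its group, so these values say little. Without it, the difference of control replicates 1 and 2 correlated with that of silenced replicates 1 and 2 at -0.01. This gives no sign of pairing for replicates 1 and 2 and leaves it open for replicate 3. With the replicate block 0 genes passed in either direction, HIF1AN had -1.06 (adjusted p = 0.668) and 1 gene lay below an unadjusted p of 0.01. Genes near the constant of 16 have little signal over background, which limits what dim genes can show.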

Other observations

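Control replicate 3 differed from the other 2 controls in single genes, the following picked from the largest differences. Compared with the mean of the other 2, KRT19 and CD24, of the nucleus pulposus marker list, were 1.63 and 1.54 higher on the log2 scale, while CA12 of the same list had -1.54 and the list as a whole lay at 0.05; the basement membrane collagens COL4A1 and COL4A2 had 1.5 and 1.25, THBS1, thrombospondin-1, 1.43, and the stem cell receptor LGR5 1.90. VCAM1, a leukocyte adhesion molecule, had a difference of -1.91, CHI3L1, a secreted chitinase-like protein, -1.72, BIRC5, survivin, -1.38, and the HIF target NDRG1 -1.28. By list, less the median of all genes, control replicate 3 differed from the other controls by -0.51 for cell cycle genes, -0.41 for NF-kB and inflammatory genes, -0.23 for HIF targets, 0.06 for cartilage matrix genes and 0.66 for cholesterol synthesis. In all, 119 genes differed over 2-fold from the mean of the other controls, against 15 and 9 for control replicates 1 and 2. NDRG1, which had a log2 change of 0.80 (SE 0.34) over the 5 arrays without silenced replicate 3, was 0.38 and 0.37 above control replicates 1 and 2 in silenced replicates 1 and 2, so part of that change rests on control replicate 3. This is 1 array, picked after its values were seen, with no test and no explanation tested.

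Silenced replicates 1 and 2 also differed in how far they lay from the controls. In silenced replicate 1, 5 genes differed over 2-fold from the mean of the controls, and in silenced replicate 2, 140. CBFA2T3 was at 7.58 and 8.97 in them against 7.19 to 7.27 in the controls, RTP5 at 5.75 and 7.09 against 5.29 to 5.61, and FOXF1 at 7.17 and 8.21 against 6.84 to 6.96, genes picked after their values were seen. The differences of silenced replicate 2 on those of silenced replicate 3, from separate control arrays, had a slope of 0.0861 and r = 0.353 across genes, which are not independent replicates, and its 336 olfactory receptor genes had a median difference of 0.14, with 70.2% of them higher.

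The tests of another cell type through ribosomal protein, olfactory receptor and proteasome genes, the later ones added after the earlier had left it open, of FIH-1 silencing in silenced replicate 3 and of that array's part in the HIF target list were chosen after the results were seen. Silenced replicate 3 stood apart from all other arrays. Rows out of order are argued against as the whole source: the 2 probe sets of a gene still correlated in this array at r = 0.335 (95% interval 0.257 to 0.408, 532 genes; 0.644 to 0.671 in the other arrays), where fully shuffled rows would give a value near 0, and of all 28869 probe sets 17.9% had a signal below 17, against 4.69% to 5.38% in the other arrays, a share that moving rows within a column leaves as it is. FIH-1 silencing is argued against as the whole source, since the differences of silenced replicate 1, where HIF1AN was also lower, had a slope of 0.00143 on those of silenced replicate 3. Silenced replicate 2, where HIF1AN was lower too, had a slope of 0.0861 with r = 0.353, so a part shared with that array stays open. Another cell type stays open, because none of its 3 tests reached the bound set for excluding it: ribosomal protein genes had -1.93 (bound -2), olfactory receptor genes 0.61 with 69.9% higher (bound 75%; 70.2% in silenced replicate 2), and of 31 proteasome subunit genes, which every nucleated cell needs, 5 or 16.1% had a signal below 17 (bound 20%; 0 in each other array), with a median difference of -3.31. Little amplified cellular RNA stays open too: olfactory receptor genes lay 1.19 above the median shift of all genes, as it predicts, but the ribosomal protein genes missed the drop of 2 that it was set to need.

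The lower HIF target list over 6 arrays may be a technical effect of silenced replicate 3. Its median without that array was 0.0349. Within that array its median difference from the controls was -2.16. Random lists of the same size and control level, 10000 in all, had a median of -1.81 there. Genes of similar brightness were thus lower too, but the list lay at percentile 6 of the random lists, so most of them fell less. The level of the list's genes is therefore not shown to account for the whole difference. Silenced replicates 1 and 2 had 0.04 and -0.05 on the list, less the median of all genes. Control replicates 1, 2 and 3 had 0.12, 0.14 and -0.23 against the other controls, so the silenced values lay between those of the controls. Because each control was set against the other controls, their values tend to fall on both sides of 0. A value near 0 is then likely to lie between them, so this comparison cannot show that silenced replicates 1 and 2 were unchanged. With control replicate 3 left out as well the median of the list was -0.03, with 26 of 40 members below 0 (camera with the preset correlation, adjusted p = 0.381). A small change in silenced replicates 1 and 2, and any effect of FIH-1 silencing within silenced replicate 3, stay open.

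The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest of the others 0, so all 10 gave as many. With a real count of 0 this outcome was fixed in advance. It gave 1 gene below an unadjusted p of 0.01, and 2 splits, the real one included, gave as many (highest other 1). It gave 8 lists past the threshold, more than the highest other of 7, so 1 split gave as many. The size of the HIF target median was 0.69, with 0.93 as the highest other and 6 splits as large. That of the Notch pathway was 0.24, with 0.46 as the highest other and 10 splits as large. Silenced replicate 3 is part of every split, so the list results carry its effect whichever way the arrays are divided. The splits therefore cannot tell the grouping apart from that array.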
